A study of Danio rerio with 8 samples.

How the data were processed

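RNA was measured in pools of whole zebrafish embryos at 26 hours post fertilisation (hpf), with 4 pools of wild-type embryos and 4 pools of maternal-zygotic (MZ) osgep G177A homozygotes, called mutant embryos here. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was depleted, cDNA was made with random primers, and the libraries were sequenced on an Illumina NovaSeq. Coding and non-coding transcripts were therefore both sampled, and a difference in the number or size of a tissue within the embryo enters the counts in the same way as a difference in expression per cell. The genotype of each library was taken from its title, and the replicate number from the same title.

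The deposited file holds RSEM expected counts per gene, 1 column per library, not scaled between libraries. Trimmomatic, STAR 2.7 and RSEM were named with the build danRer11 per the submitters' processing notes, while their order, settings, the gene annotation and the use of strand are not given in the sources used here. RSEM divides reads that match several places among them, so near-identical genes share an estimate, and reads from overlapping or antisense genes may not be separated. The table has 36351 rows, of which 7265 carry no Ensembl identifier, 458 carry a symbol used by another row and 4148 have no count in any library. The totals ranged from 21290942 to 27675104 counts per library. Comparison of counts, over the genes with more than a few counts in a pair of libraries, found no pair within sampling noise. The lowest chi-square per degree of freedom was 6.14, for wild-type pools 1 and 3. The next was 24.3, for mutant pools 3 and 4. Each library was therefore kept as a replicate, though separate libraries from the same pool could also exceed sampling noise. The labels describe pools and do not tie them to separate clutches, so the p-values measure the spread between these pools.

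The expected counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr at its defaults, which left 22467 genes. Libraries were scaled by TMM, and genotype was tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05 on the adjusted p. Log2 fold changes are mutant minus wild type. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM after TMM scaling, given as mean ± SD of 4 libraries. Ratios of genes with few counts in 1 genotype were computed from the summed counts, scaled for depth, with a 95% exact interval that covers counting error only, and a group with no count was set to 3 counts over the whole group.

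Before the data were examined, 39 gene lists, the main design, the alternatives and the rule for naming genes were fixed. Of the 883 listed symbols, 866 were matched to the table, 833 by symbol and the rest through Ensembl identifiers or RefSeq synonyms, while 3 lists were filled by a name pattern. Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The named genes are osgep, the 10 genes with the largest and the 10 with the lowest log2 fold change among changed genes with an average log2 CPM of at least 0 and no overlap between the genotypes, the 5 genes with the smallest p per direction, and up to 4 members per list with the smallest p. Clone and locus identifiers were passed over in this rule, 23 among the largest rises and 24 among the largest falls, together with 1 and 3 among the smallest p. Of the genes this rule names, 2 are not reported here and were left out of the screen for libraries far from the others of their genotype.

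Gene order and chromosome membership came from the RefSeq table of another assembly, GRCz12tu, which placed 80.3% of the tested genes and 84.1% of the changed genes. That table was used only for names and for which genes share a chromosome or lie next to each other, since the count table uses another build, and no coordinates are given. Windows in base pairs around osgep and the planned comparison of fold change with the share of ANN codons were not run, because neither matching coordinates nor coding sequences were used here.

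The procedure was tested on simulated data first. Counts were drawn for the 22467 genes from the means, dispersions and depths of these libraries, with 200 genes changed. In this simulated comparison of mutant with wild type, edgeR recovered 4% of the genes changed by 1.5-fold, 44% of those changed by 2-fold, 90% at 4-fold and 88% at 8-fold. It called 6 of the 21793 unchanged genes left after the same filter was applied to the simulated counts. A simulated list of 30 genes raised together was called by camera, and an unchanged list of the same size was not. The counts of each gene were drawn independently, so this check does not show how often camera calls unchanged lists whose genes move together. Genes changed by 1.5-fold were thus often missed in the simulation. These rates need not hold for the real data, where far more genes were called and the adjustment was therefore less strict.

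The alternatives were other size factors (the median-of-ratios factors of DESeq2, and upper quartile), no filter and a stricter filter (at least 10 counts in 4 or more libraries), each library left out in turn, the replicate number as a block, scaling without the top 20 and the mitochondrially encoded genes, 1 surrogate variable from sva 3.50.0, DESeq2 1.42.0, limma-voom, other thresholds, and removal of the genes on the osgep chromosome. Further alternatives were chosen after seeing the data: leaving out 2 libraries that stood apart, the ribosomal protein share as a covariate, and windows of neighbouring genes around osgep. All 35 ways of parting the 8 libraries into 4 and 4 were refitted as a test of chance.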

Results

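The series asks how RNA levels differ between wild-type zebrafish embryos and embryos whose mother and zygote both carried only the G177A allele of osgep. The gene encodes the catalytic subunit of the KEOPS complex, which makes the modified base threonylcarbamoyladenosine in tRNAs that read codons starting with A. Whole-embryo pools at 26 hpf were sequenced, 4 per genotype, with 21290942 to 27675104 expected counts per library. Totals did not separate the genotypes (exact two-sided permutation test p = 0.257). Levels below are CPM as mean ± SD of 4 libraries per genotype.

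The transcript of osgep itself (ENSDARG00000045846) was lower in the mutant pools. It measured 19.2 ± 3.24 CPM in wild type and 10.7 ± 2.25 CPM in the mutant, which is 55.9% of the wild-type level. All 4 mutant libraries lay below all 4 wild-type libraries (log2 fold change −0.84, SE 0.18, adjusted p = 0.00826 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An exact permutation test of log2 CPM gave p = 0.0286, the smallest that 4 against 4 libraries allow. The count table does not separate alleles, so this level does not by itself check the genotype. Of the 6 measured genes on the list of KEOPS and its pathway, 2 rose and 1 fell, with the same counts adjusted over the list alone. Those that rose were yrdc, which makes the precursor of the modification (19.4 ± 1.49 to 34.1 ± 1.31 CPM), and osgepl1, the mitochondrial relative of osgep (0.869 ± 0.266 to 2.30 ± 0.4998 CPM). The subunit gene tp53rk did not pass (log2 fold change −0.26, SE 0.10), and the list as a whole did not pass either (camera adjusted p = 0.592).

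The mutant pools combined a rise of ATF4 target genes with a fall of skeletal muscle genes, and these are the 2 lists whose calls also held with an estimated correlation between genes. Most lens and neuron genes measured fell as well, though as lists they did not pass with an estimated correlation (adjusted p = 0.132 and adjusted p = 0.297 with an estimated correlation). The amino acid transporter genes slc3a2b and slc7a5, the serine synthesis gene phgdh and most tRNA synthetase genes rose, and fast muscle genes such as myhz1.1 and tnni2a.4 fell. In total 7225 of the 22467 tested genes changed, 3560 higher and 3665 lower in the mutant. Of these, 3463 differed by at least 2-fold, 1712 higher and 1751 lower. The genotypes did not overlap in 33.7% of the tested genes, where chance gives 2.86%.

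The smallest p belonged to igfbp1a, which encodes an insulin-like growth factor binding protein (3.27 ± 0.379 to 141 ± 9.32 CPM). They were joined by the amino acid transporter genes slc3a2b (14.1 ± 1.33 to 197 ± 14.8 CPM) and slc7a5 (33.8 ± 2.82 to 337 ± 25.6 CPM). The others were phgdh, the first enzyme of serine synthesis (76.3 ± 3.96 to 773 ± 43.0 CPM), and trib3, a pseudokinase gene (46.3 ± 0.862 to 223 ± 8.68 CPM). Their adjusted p ran from 2.29e-07 for igfbp1a to 1.28e-06 for trib3 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. On the lower side they were tnni2a.4, pvalb1, myhz1.1, mylpfb and the reductase gene ptgr1, which went from 82.8 ± 7.74 to 18.4 ± 1.203 CPM.

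**Figure D1:**
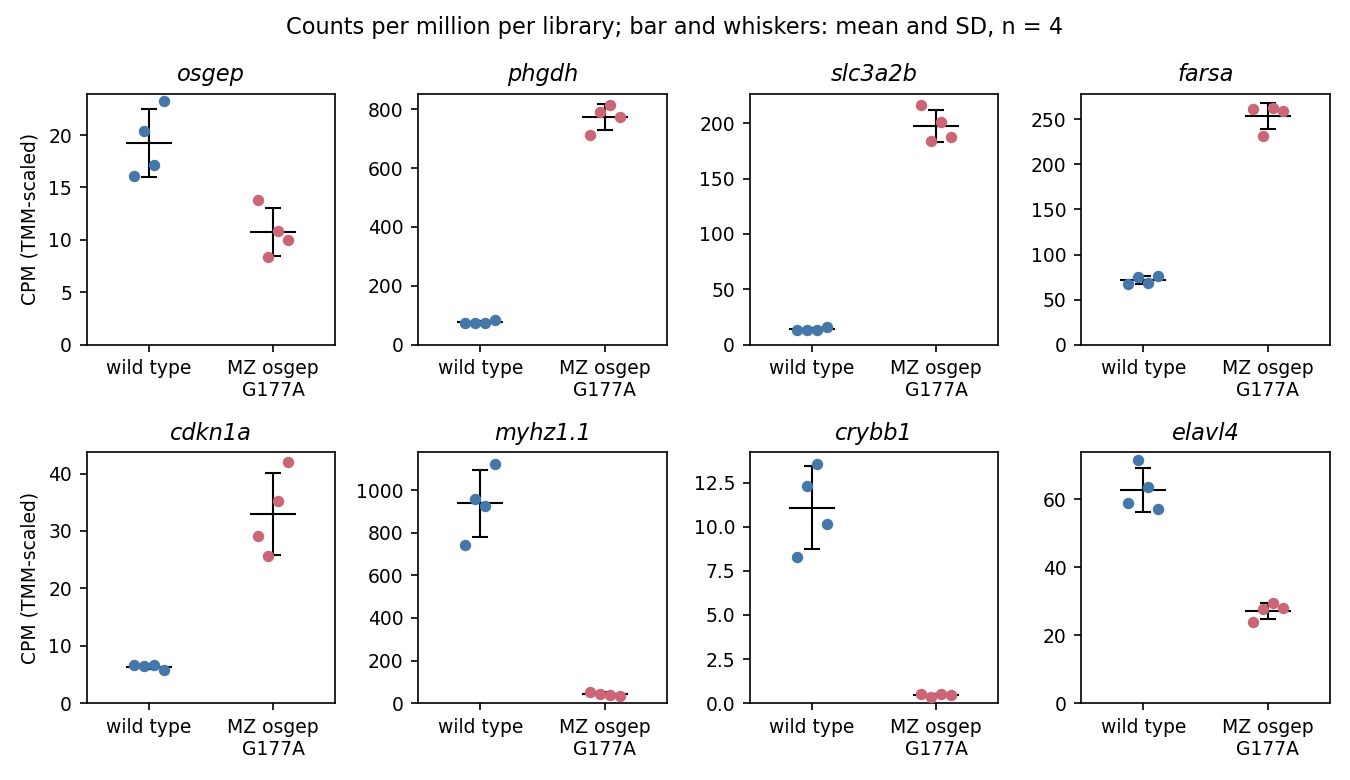
TMM-scaled CPM (vertical axes, linear from 0) of 8 genes in the 4 wild-type and 4 mutant libraries. Points are libraries, and the bar with whiskers is the mean with SD. phgdh stands at 76.3 CPM in wild type and 773 CPM in the mutant, and myhz1.1 at 938 and 42.4 CPM.

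Several of the largest differences were close to all or none. hephl1b, a ferroxidase-like gene, had 1 count over the wild-type libraries and 5019 over the mutant libraries, a depth-scaled ratio of 4751 with a counting interval from 852.3 to 187700. ggact.3 had no count in wild type and 1122 in the mutant, 354-fold higher when the wild-type group is set to 3 counts. Its counting interval started at 287.4 and had no upper end. mchr1b, ifnphi1, parp9 and ms4a17a.10 had 5, 1, 5 and 6 wild-type counts against 1261, 262, 599 and 396 mutant counts. The neutral amino acid transporter gene slc6a15 (1.71 ± 0.439 to 166 ± 27.3 CPM), irf3 (0.155 ± 0.0609 to 13.7 ± 7.48 CPM) and fkbp16 (0.163 ± 0.0774 to 11.0 ± 1.35 CPM) completed the largest rises together with rrm2. The ribonucleotide reductase gene rrm2 stood at 3.29 ± 1.38 CPM in wild type and 336 ± 44.2 CPM in the mutant. This value is uncertain, since a second row with the reference name RRM2, looked up after the values were seen, went from 828 ± 50.01 to 395 ± 85.4 CPM. The sum of both rows was 831 ± 49.3 CPM in wild type and 732 ± 70.4 CPM in the mutant (exact permutation test p = 0.0857).

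Among the largest falls, 6 encode proteins of muscle: the calcium-binding parvalbumins pvalb1, pvalb2 and pvalb4, the phosphofructokinase pfkmb, the fast troponin I tnni2a.4 and the calsequestrin casq1b. pvalb1 had 3609 counts over the wild-type libraries and 8 over the mutant libraries, a ratio of 477 (counting interval 241.6 to 1105). pvalb2 went from 168 ± 33.6 to 2.57 ± 0.815 CPM and casq1b from 11.96 ± 2.58 to 0.172 ± 0.129 CPM. pfkmb and pvalb4 had 582 and 730 wild-type counts against 5 and 10 mutant counts. The others were gabrz with 335 against 4 counts, limd1b with 361 against 11, mlpha, a melanosome transport gene, with 255 against 8, and nmrk2, a nicotinamide riboside kinase gene, at 35.3 ± 10.16 and 1.08 ± 0.428 CPM. A second row with the reference name NMRK2, mibp2, looked up after the values were seen, stood at 339 ± 70.7 and 353 ± 91.4 CPM and did not pass, so the fall concerns the smaller of these 2 rows. Other rows that share a reference name with a gene of this rule moved the same way: mylpfa (1395 ± 285 to 182 ± 41.2 CPM), tnni2b.1 (538 ± 66.6 to 309 ± 23.5 CPM), casq1a (8.45 ± 1.88 to 0.938 ± 0.366 CPM) and pfkma (1.63 ± 0.482 to 0.0915 ± 0.0403 CPM) fell. For ggact.3 they were ggact.2 (3.68 ± 1.47 to 10.7 ± 1.09 CPM) and ggact.1 (0.331 ± 0.298 to 1.47 ± 0.243 CPM), which rose. These copies were looked up after the values were seen, and the division of reads among similar copies stays uncertain.

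Of the 39 gene lists, 16 passed camera at an adjusted p under 0.05, 11 higher and 5 lower in the mutant. The list of ATF4 targets of the integrated stress response, a programme switched on when translation initiation is restrained, stood first. Of its 35 measured genes 30 rose and none fell, with 30 also adjusted over the list alone, and the median log2 fold change was 2.26 (camera adjusted p = 3.82e-85, and adjusted p = 0.000202 with an estimated correlation). The members that did not pass were eif4ebp1, eif4ebp2, vldlr, nupr1b and psph, singled out after their values were seen. Of the 16 cytoplasmic aminoacyl-tRNA synthetases, which charge tRNAs, 15 rose, and 16 adjusted over the list alone, with a median of 1.47. farsa rose from 71.7 ± 4.48 to 254 ± 14.8 CPM, cars from 49.4 ± 5.50 to 157 ± 3.23 CPM, yars from 79.8 ± 4.89 to 227 ± 17.0 CPM and gars from 179 ± 18.7 to 499 ± 24.4 CPM (camera adjusted p = 5.26e-22, and adjusted p = 0.0855 with an estimated correlation). Among 40 translation factors, 13 rose and 8 fell, with the same counts adjusted over the list alone, and the median was 0.12 (camera adjusted p = 0.0076, and adjusted p = 0.433 with an estimated correlation). The risers with the smallest p were eif2ak1, an eIF2 kinase gene (12 ± 1.07 to 40.9 ± 1.59 CPM), and the eIF2B subunit genes eif2b1 (24.7 ± 1.26 to 76.7 ± 6.82 CPM), eif2b4 (42.4 ± 3.56 to 128 ± 8.55 CPM) and eif2b2 (31.8 ± 4.65 to 102 ± 7.78 CPM).

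The list of the unfolded protein response of the endoplasmic reticulum did not move as a group. Of 25 genes 4 rose and 9 fell, and adjusted over the list alone the counts were the same (camera adjusted p = 0.75). herpud1 (24.9 ± 1.68 to 48.9 ± 2.73 CPM), pdia6 (51.6 ± 5.10 to 102 ± 11.6 CPM) and xbp1 (189 ± 17.1 to 362 ± 18.7 CPM) rose, and dnajc3b fell (46.5 ± 3.90 to 21.4 ± 3.60 CPM). Heat shock chaperones went both ways, 7 of 23 higher and 4 lower (7 and 5 adjusted over the list alone), with a median of −0.049 against an upward camera direction (adjusted p = 0.47). Their largest named change was serpinh1b, a collagen chaperone gene, from 204 ± 61.0 to 1433 ± 382 CPM. The hypoxia list held 6 higher and 6 lower of 27, in both adjustments (camera adjusted p = 0.0943), with pfkfb4b higher (29.2 ± 4.57 to 145 ± 23.7 CPM) beside igfbp1a, and ldha (40.9 ± 5.17 to 14.4 ± 2.08 CPM) and hk1 (147 ± 6.04 to 86.8 ± 5.08 CPM) lower.

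Targets of p53 rose in 12 of 24 cases and fell in 1. Adjusted over the list alone, 16 rose and 3 fell. The median was 1.05 (camera adjusted p = 6.99e-10, and adjusted p = 0.0678 with an estimated correlation). The cell cycle inhibitor gene cdkn1a went from 6.38 ± 0.400 to 33.0 ± 7.16 CPM, mdm2 from 36.8 ± 1.04 to 98.2 ± 15.8 CPM, tp53inp1 from 38.8 ± 2.32 to 106 ± 15.2 CPM and the death receptor gene fas from 0.251 ± 0.0499 to 3.74 ± 0.2498 CPM. Of 22 genes of the apoptosis machinery 8 rose and 3 fell, and 9 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 0.00696, and adjusted p = 0.18 with an estimated correlation). casp9 (3.81 ± 0.361 to 15.7 ± 1.37 CPM), bbc3 (3.64 ± 0.743 to 18.1 ± 5.08 CPM) and diablob (15.9 ± 2.19 to 45.9 ± 7.02 CPM) rose. Cell cycle genes did not move as a group, with 1 of 30 higher (rrm2) and 5 lower in both adjustments, a median of −0.11 and a mean of 0.08 (camera adjusted p = 0.72). cdk1 (101 ± 8.28 to 65.8 ± 3.91 CPM), ccnb1 (199.7 ± 17.5 to 117 ± 15.6 CPM) and mki67 (696 ± 97.9 to 429 ± 42.2 CPM) fell. DNA damage repair genes rose in 4 of 24 cases, or 3 adjusted over the list alone (camera adjusted p = 0.428), among them h2afx (33.1 ± 1.33 to 55.2 ± 4.07 CPM) and fancd2 (30.9 ± 5.14 to 48.1 ± 4.49 CPM). Telomere maintenance genes rose in 5 of 17 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.463), with nhp2 going from 75.3 ± 9.53 to 135 ± 15.0 CPM.

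The inflammation and immediate early list had 14 of 24 genes higher and 2 lower, and 15 and 2 adjusted over the list alone (median 0.66, camera adjusted p = 2.49e-05, and adjusted p = 0.297 with an estimated correlation). fosl1a (1.72 ± 0.416 to 37.5 ± 25.1 CPM), fosab (1.67 ± 0.436 to 18.3 ± 8.21 CPM), ptgs2b, a prostaglandin synthase gene (7.24 ± 0.808 to 49.5 ± 10.1 CPM), and atf3, which also stands on the ATF4 list (5.66 ± 1.097 to 49.6 ± 9.34 CPM), rose. Of 14 myeloid genes 5 rose and none fell in both adjustments. The median stood at 1.33 (camera adjusted p = 0.0118, and adjusted p = 0.547 with an estimated correlation). Risers included spi1b, a myeloid transcription factor gene (1.55 ± 0.469 to 6.30 ± 1.15 CPM), and cybb, a phagocyte oxidase gene (2.62 ± 0.810 to 6.81 ± 1.03 CPM). The myeloid call ended with 1 surrogate variable (adjusted p = 0.0582) and with the ribosomal protein share as a covariate (adjusted p = 0.0761). Over all alternatives its camera adjusted p ran from 0.000464 to 0.547. Interferon response genes went both ways, 4 of 16 higher and 3 lower in both adjustments (camera adjusted p = 0.346). irf3, isg15 (9 wild-type against 262 mutant counts) and irf7 (4.58 ± 1.54 to 10.6 ± 2.00 CPM) were higher, and mxc was lower with 86 wild-type and 12 mutant counts.

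Among the lists that fell, skeletal muscle had the smallest camera p and the lens list the lowest median. Of the 36 muscle genes measured 27 fell and none rose, or 28 adjusted over the list alone, and the median log2 fold change was −1.91 (camera adjusted p = 7.99e-40, and adjusted p = 0.0461 with an estimated correlation). The fast myosin heavy chain gene myhz1.1 went from 938 ± 156 to 42.4 ± 8.45 CPM, tnni2a.4 from 72.3 ± 18.3 to 0.730 ± 0.115 CPM and the fast myosin light chain gene mylpfb from 59.3 ± 13.7 to 2.41 ± 0.283 CPM. The adjusted p of these were 3.71e-06, 1.70e-06 and 3.92e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the lens list 11 of 14 genes fell and none rose, while adjusted over the list alone 11 fell and 1 rose (median −2.81, camera adjusted p = 1.12e-08, and adjusted p = 0.132 with an estimated correlation). The lens crystallin genes crybb1 (11.1 ± 2.35 to 0.466 ± 0.0806 CPM), cryba2a (4.56 ± 1.37 to 0.219 ± 0.0649 CPM), crybb1l1 (6.18 ± 2.52 to 0.364 ± 0.176 CPM) and crybb1l2 (7.57 ± 1.29 to 1.23 ± 0.306 CPM) were among them.

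Of 28 genes of postmitotic neurons 17 fell and 1 rose, or 19 and 1 adjusted over the list alone (median −0.86, camera adjusted p = 4.35e-08, and adjusted p = 0.297 with an estimated correlation). The RNA-binding protein gene elavl4 (62.7 ± 6.48 to 27.2 ± 2.36 CPM), the synaptic gene snap25a (53.9 ± 11.3 to 14.7 ± 2.06 CPM), the tubulin gene tubb2 (22.5 ± 1.05 to 8.85 ± 1.43 CPM) and the neurofilament gene nefmb (11.9 ± 1.80 to 2.54 ± 0.745 CPM) fell. Neural crest and pigment genes fell in 10 of 23 cases and rose in 1, or 11 and 1 adjusted over the list alone (median −0.56, camera adjusted p = 0.00322, and adjusted p = 0.297 with an estimated correlation). aox5 (28.7 ± 3.08 to 10.3 ± 1.62 CPM) and the kinase gene ltk (4.71 ± 0.827 to 1.44 ± 0.269 CPM) fell with mlpha, while snai2 rose (50.3 ± 0.189 to 82.1 ± 8.503 CPM). Among 49 hox genes 8 fell and 1 rose, or 6 and 1 adjusted over the list alone (median −0.34, camera adjusted p = 0.0153, and adjusted p = 0.787 with an estimated correlation). Those with the smallest p were the posterior genes hoxb13a (5.85 ± 1.86 to 1.07 ± 0.172 CPM), hoxc13a (20.4 ± 6.36 to 7.08 ± 0.672 CPM), hoxc13b (14.1 ± 5.66 to 4.23 ± 1.42 CPM) and hoxa13a (9.89 ± 4.03 to 3.61 ± 1.04 CPM). The hox call ended without wild-type library 1 (camera adjusted p = 0.0585) and without mutant library 2 (0.103). It also ended with the ribosomal protein share as a covariate (camera adjusted p = 0.075) and with fry (adjusted p = 0.134). Over all alternatives its adjusted p ran from 9.36e-06 to 0.787.

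**Figure D2:**
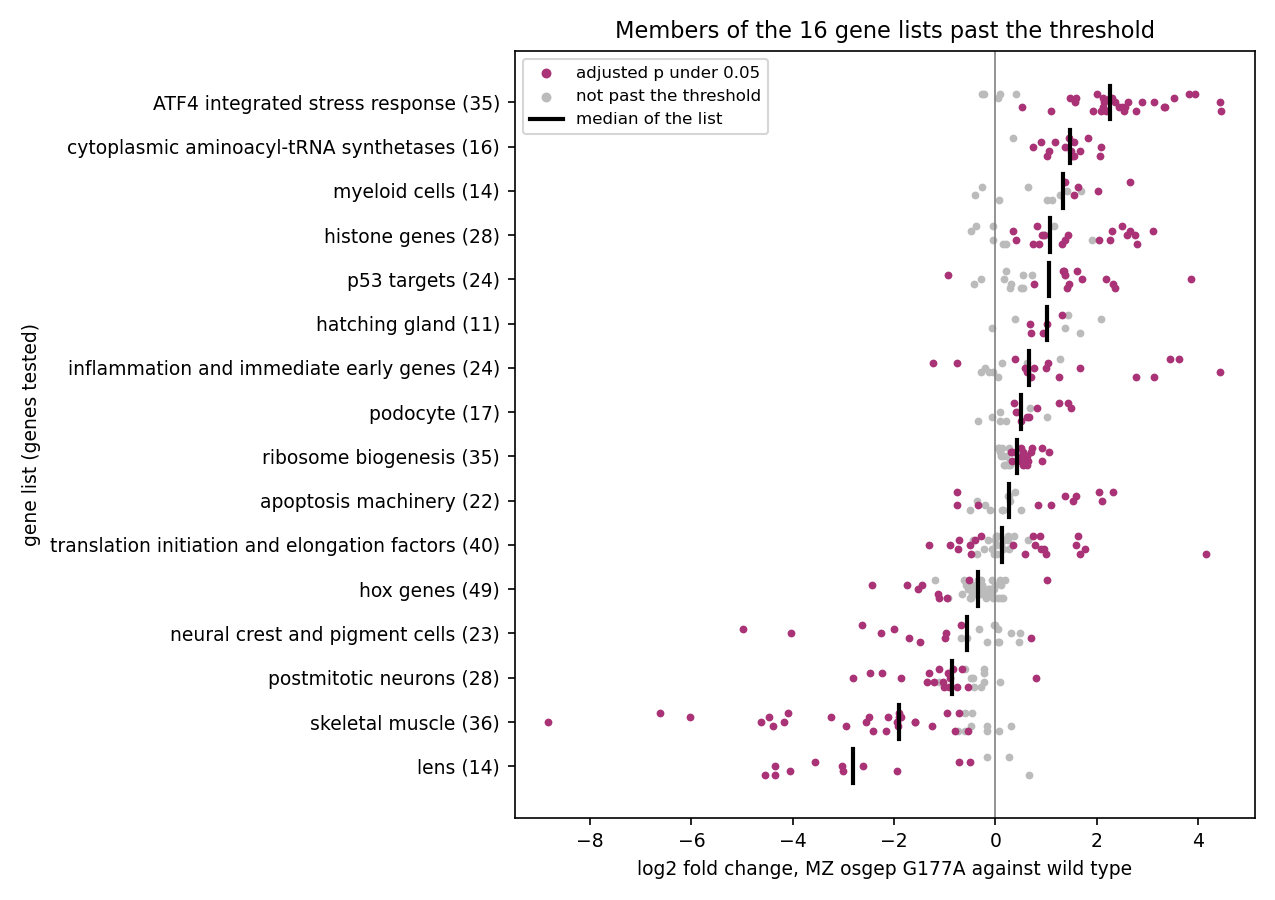
Log2 fold change of mutant against wild type (horizontal axis) for the members of the 16 lists that passed camera, 1 row per list with the number of genes tested. Each point is a gene, coloured where its adjusted p is under 0.05, and the bar is the median of the list. The ATF4 list has its median at 2.26 and the lens list at −2.81.

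Neural and retinal progenitor lists did not pass camera as groups, but both passed fry (adjusted p = 0.0278 and adjusted p = 0.00406 with fry). Of 25 neural progenitor genes 3 rose and 10 fell in both adjustments (camera adjusted p = 0.0695), with her4.2 (104 ± 23.5 to 43.1 ± 7.49 CPM) and fabp7a (76.0 ± 12.6 to 39.2 ± 9.62 CPM) lower and nes (122 ± 1.86 to 161 ± 11.3 CPM) higher. Of 19 retinal genes 2 rose and 7 fell, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.0617), with rorb (19.3 ± 2.28 to 7.55 ± 0.673 CPM) and foxn4 (15.9 ± 1.06 to 7.93 ± 0.789 CPM) lower and otx5 (1.91 ± 0.334 to 4.94 ± 0.900 CPM) higher.

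Histone genes rose in 19 of 28 cases with none lower, in both adjustments (median 1.07, camera adjusted p = 3.97e-06, and adjusted p = 0.363 with an estimated correlation). They included the linker histone genes h1fx (18.8 ± 2.31 to 48.6 ± 9.31 CPM) and h1f0 (186 ± 11.99 to 335 ± 26.3 CPM). Histone genes exist in near-identical copies, so single members of this list are uncertain. Ribosome biogenesis genes rose in 19 of 35 cases with none lower, or 20 adjusted over the list alone. Their median was 0.44 (camera adjusted p = 2.17e-05, and adjusted p = 0.545 with an estimated correlation). Examples are imp4 (40.2 ± 1.99 to 76.1 ± 8.44 CPM) and utp4 (45.6 ± 6.48 to 86.1 ± 4.40 CPM). Of 82 cytoplasmic ribosomal protein genes only rps27l, which also stands on the p53 list, passed in either adjustment (20.3 ± 7.64 to 92.5 ± 32.1 CPM), and the list did not (median −0.13, camera adjusted p = 0.463). Hatching gland genes rose in 5 of 11 cases with none lower, in both adjustments. The median was 1.02 (camera adjusted p = 0.00322, and adjusted p = 0.483 with an estimated correlation). Among them were the hatching enzyme gene he1.3 (34.9 ± 10.4 to 71.0 ± 17.6 CPM) and klf17 (15.8 ± 7.73 to 39.4 ± 6.42 CPM).

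Genes of the podocyte list, named for the filtering cells of the kidney, rose in 9 of 17 cases with none lower, in both adjustments (median 0.50, camera adjusted p = 0.00811, and adjusted p = 0.371 with an estimated correlation). The slit diaphragm gene nphs1 went from 1.45 ± 0.441 to 4.09 ± 0.870 CPM and kirrel1b from 6.05 ± 0.494 to 10.6 ± 0.866 CPM. vegfaa, which also stands on the hypoxia list, went from 24.6 ± 5.17 to 59.0 ± 10.6 CPM. Pronephric tubule genes rose in 5 of 20 cases and fell in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0855), with gata3 (33.7 ± 2.55 to 58.5 ± 8.48 CPM) and hnf1ba (12.3 ± 3.805 to 24.5 ± 3.86 CPM) higher.

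Blood, vessel and heart lists held changes in both directions and did not pass. Among 26 erythroid genes 6 rose and 7 fell, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.428). The early regulators gata1a (3.77 ± 1.06 to 9.77 ± 0.516 CPM) and tal1 (25.0 ± 1.78 to 40.6 ± 3.79 CPM) rose, and aqp1a.1 fell (17.6 ± 3.39 to 9.57 ± 0.577 CPM). Among 22 endothelial genes 6 rose and 7 fell in both adjustments (camera adjusted p = 0.677), with etv2, an early vascular regulator, higher (20.3 ± 4.00 to 52.4 ± 5.99 CPM) and aqp8a.1 lower (6.94 ± 0.396 to 2.72 ± 0.420 CPM). Of 13 heart genes 5 rose and 2 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.53), with nkx2.5 higher (1.51 ± 0.324 to 4.16 ± 1.19 CPM) and mybpc3 lower (18.2 ± 3.02 to 2.48 ± 1.16 CPM).

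The epidermal list had 7 of 29 genes higher and 6 lower, or 8 and 8 adjusted over the list alone (median 0.27, mean −0.046, camera adjusted p = 0.822), and the basal keratin gene krtt1c19e fell from 18.9 ± 6.71 to 1.82 ± 0.451 CPM. Of 26 fin and matrix genes 5 rose and 7 fell, or 7 and 7 adjusted over the list alone (median 0.006, mean −0.029, camera adjusted p = 0.612). The actinodin genes of the fin fold, and1 (17.5 ± 7.53 to 2.67 ± 0.677 CPM) and and2 (7.97 ± 3.51 to 1.13 ± 0.212 CPM), fell. Of 18 notochord and floor plate genes 4 rose and 2 fell in both adjustments (camera adjusted p = 0.428), with loxl5b higher (10.8 ± 0.865 to 48.2 ± 5.94 CPM) and epyc lower (13.6 ± 4.02 to 1.41 ± 0.986 CPM). Circadian genes rose in 13 of 32 cases and fell in 4, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.0583), among them cry1ab (6.59 ± 0.525 to 11.7 ± 0.783 CPM). Germ line genes rose in 6 of 14 cases and fell in 2 in both adjustments (camera adjusted p = 0.368), with nanos3 higher (1.93 ± 0.663 to 5.14 ± 0.672 CPM). Of 23 cholesterol and fatty acid synthesis genes 2 rose and 5 fell in both adjustments (camera adjusted p = 0.462), with hmgcra, the rate-limiting enzyme, higher (1.28 ± 0.278 to 6.54 ± 1.08 CPM).

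Libraries also differed within each genotype. The first principal component held 54.0% of the variance and parted the genotypes, and the second held 28.8% and ran within them, with wild-type library 4 lowest and mutant library 1 highest. Ribosomal protein genes took 16.04%, 11.8%, 14.8% and 8.91% of counts in wild-type libraries 1 to 4 and 16.7%, 8.11%, 9.88% and 11.2% in mutant libraries 1 to 4 (exact permutation test p = 0.6). Mitochondrially encoded genes took 4.39 ± 1.46% in wild type and 2.98 ± 1.38% in the mutant (SD, n = 4 each, exact permutation test p = 0.171). In that list 2 of 12 genes fell, or 0 adjusted over the list alone (camera adjusted p = 0.0583). These were mt-nd2 (2575 ± 977 to 1019 ± 598 CPM) and mt-nd1 (2927 ± 1070 to 1213 ± 700 CPM), whose calls ended in most fits that left out 1 library. The yolk syncytial layer and liver list took 0.176%, 0.135%, 0.165% and 0.738% in the wild-type libraries and 0.589%, 1.76%, 0.538% and 0.449% in the mutant libraries (exact permutation test p = 0.114). Of its 25 genes 5 rose and 2 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.0777), and gata6 went from 4.06 ± 2.25 to 22.2 ± 16.9 CPM.

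**Figure D3:**
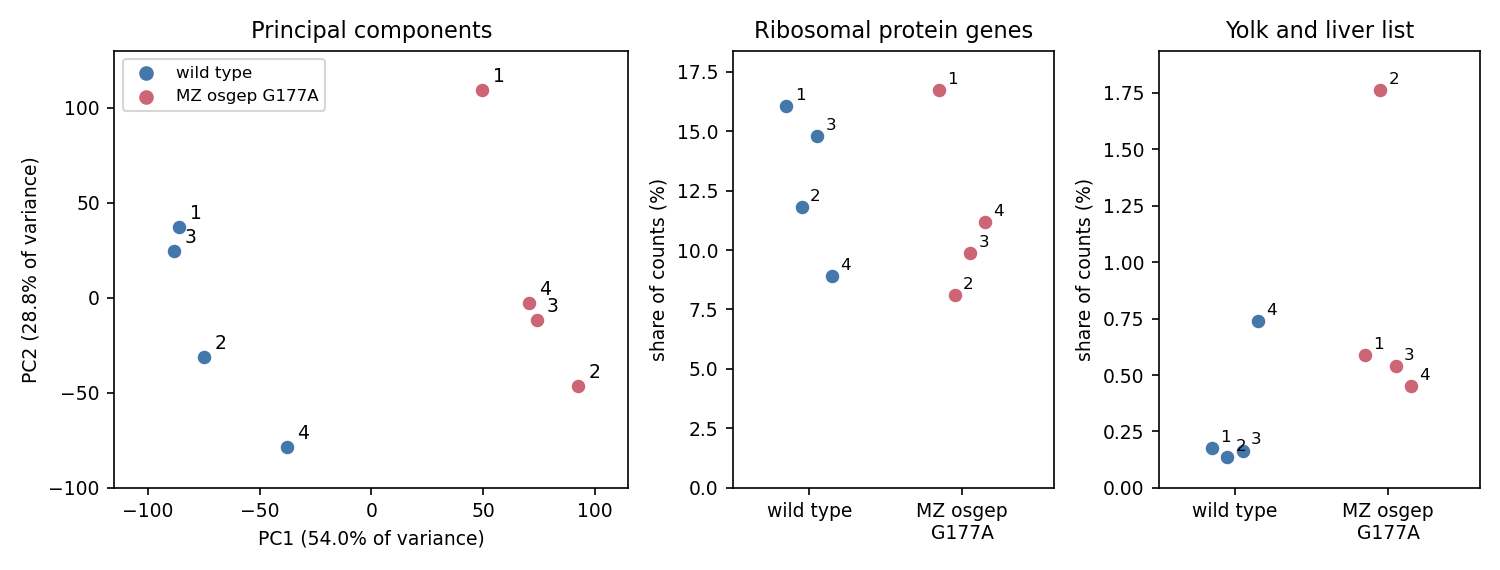
Left, the first and second principal components of log2 CPM for the 8 libraries, numbered by replicate, with the share of variance on each axis. Middle and right, the percentage of counts in each library from ribosomal protein genes and from the yolk and liver list. Wild-type library 4 holds 0.738% yolk and liver counts against 0.135% to 0.176% in the other wild-type libraries.

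Genes on the chromosome of osgep were called less often than genes elsewhere. There 222 of 784 placed genes changed (28.3%), against 5851 of 17265 on other chromosomes (33.9%, odds ratio 0.77, 95% interval 0.65 to 0.90, Fisher's exact test, two-sided, p = 0.00116). The test treats genes as independent. Other chromosomes were not compared singly, so the usual spread between chromosomes is not known here. In windows chosen after seeing the data the call ended for the nearest 50 genes on either side (odds ratio 0.69, Fisher's exact test p = 0.112) and the nearest 200 (odds ratio 0.83, p = 0.144), but not for the nearest 100 (odds ratio 0.71, p = 0.0348). The window of the nearest 200 held 307 genes, as fewer than 200 placed genes lay on 1 side.

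The number of changed genes rose by over 1.5 times, from 7225 to 12084 with 1 surrogate variable, and, in fits chosen after seeing the data, to 11574 with the ribosomal protein share as a covariate and to 11385 without wild-type library 4 and mutant library 1. Of the 7225 genes, 99.8%, 99.7% and 94.7% were called again in the same direction in these fits.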

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

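The tests of the RRM2 copies and of the cell cycle genes were chosen only after the rrm2 result was seen, and the lists of segmentation and early myogenic genes, the covariate and the splits per list after the first results. Also chosen after their values were seen were the test of the smallest p of any list, the contrast with myf6 moved and the count of unplaced genes. Of 334 sets of 4 values tested for a library far from the other 3 of its genotype, 27 had one (8.08%), where chance gives about 1 in 20. Wild-type library 4 held 11 of these, wild-type library 1 held 7, mutant library 1 held 6 and mutant library 2 held 3. For 2 of those in wild-type library 4 (hephl1b and ifnphi1) a single count among zeros fixes the outcome, and without sets of that kind 25 of 331 had one (7.55%), 9 of them in wild-type library 4.

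Wild-type library 4 had a yolk and liver share of 0.738% (others 0.135% to 0.176%), and in CPM 0.03916 for both hephl1b and ifnphi1 (others 0), 16.06 for slc3a2b (others 13.34 to 13.47), 82.19 for phgdh (73.63 to 74.99), 38.53 for fancd2 (27.2 to 29.06) and 163 for anxa1b (101.3 to 107.5). It also had 33.25 for ldha (42.73 to 44.58), 7.244 for hnf1bb (2.781 to 3.234), 13.59 for eif2ak1 (11.28 to 11.57) and 21.11 for apoea (3.407 to 5.332). Wild-type library 1 had 12.5 CPM for aqp1a.1 (others 19.03 to 19.43), 913.8 for col1a1a (1097 to 1122), 95.32 for agr1 (97.59 to 97.82), 483.5 for histh1l (446 to 450.3), 7.298 for atf3 (4.973 to 5.287), 2.316 for fosab (1.381 to 1.527) and 12.11 for loxl5b (10.3 to 10.46). Mutant library 1 had a mitochondrial share of 5.023% (others 1.996% to 2.498%), with 1907 CPM for mt-nd2 (609.8 to 800.3) and 2255 for mt-nd1 (746.3 to 960). It had 125.5 CPM for slc6a15 (others 175.4 to 182.2), 2.23 for dnd1 (1.685 to 1.714) and 69.35 for snai2 (85.54 to 87.04). Mutant library 2 had a yolk and liver share of 1.761% (others 0.4494% to 0.5893%), 231.7 CPM for farsa (259 to 262.7) and 47.45 for gata6 (11.96 to 16.28).

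Genes of differentiated muscle were lower in the mutant as a set, while genes that act early in the muscle lineage were not lower as a set. The fall was not shared by all muscle genes: 27 of the 36 listed fell. The slow myosin genes smyhc1 (log2 fold change −0.1598) and smyhc2 (−0.1645), singled out after their values were seen, did not pass (adjusted p = 0.697 and 0.74 in edgeR's quasi-likelihood test). The 13 early myogenic regulators had a median log2 fold change of 0.05193 against −1.929 for the 33 other genes of the skeletal muscle list. The difference was 1.981 (permutation test over genes, which treats them as independent, p = 0.0025). With myf6, a regulator that fell, moved to their side and the receptor gene chrna1 left out, the medians were −0.01925 and −1.942 (permutation test p = 0.0027). Fewer cells of the muscle lineage would lower both sets only if the regulators were read from muscle alone. Whole-embryo pools do not separate muscle from other tissues, so this explanation stays open. The median of the skeletal muscle list was at most −1.778 over the fits without 1 library and the fit with the ribosomal protein share. This argues against 1 library as the source of the fall. Library composition in general stays open, because the ribosomal protein share did not separate the genotypes (exact permutation test p = 0.6). Slower development of the mutant pools could lower late genes too, and it stays open: the 19 segmentation and tailbud genes had a median of 0.01035, with 4 higher and 2 lower. Stage markers that move both ways do not decide it, and no stage was measured per pool here.

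Among genes with an average log2 CPM of at least 0, 87 had at most 12 counts over 1 genotype and were called, 46 with so few counts in wild type and 41 in the mutant. Variants linked to osgep are argued against as the whole cause, since 3 of the 47 genes with a place in the reference (6.383%) lay on its chromosome, against 4.338% of other genes (Fisher's exact test p = 0.458), and 44 lay elsewhere. For the 40 genes without a place, linked variants and regulation cannot be told apart, because their chromosome is not known here. Haplotypes that differ elsewhere between the stocks may also give such a pattern: 2 adjacent pairs lay elsewhere (median 0 in 10000 random draws, as many in a share of 0.0049), more than the draws' upper limit of 1, but with 54.02% of the genes placed the check is void under a limit of 80% that replaced a first limit of 50% after the values were seen, so this stays open. For rrm2, more cells in S phase would raise the other cell cycle genes, whose median log2 fold change was −0.124. Histone genes rose in 19 of 28 cases, however, so more cells in S phase is not settled. Reads divided between copies named RRM2 remain a candidate explanation for rrm2, as the summed level had a ratio of 0.88 (sequence similarity was not examined here).

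With the ribosomal protein share as a covariate, 99.7% of the changed genes were called again in the same direction. This cannot decide whether library composition caused the changes, because the share did not separate the genotypes (exact permutation test p = 0.6). The yolk and mitochondrial shares were not used as covariates. Of 35 splits of the 8 libraries, only the real split (1 of them) gave as many as 7225 changed genes and 3463 of at least 2-fold. The highest other counts were 2641, in the split that trades wild-type library 4 for mutant library 1, and 1120. Chance is thus argued against for both counts, though 1 of 35 is the smallest share that this design allows. For the number of 16 gene lists chance stays open, as 12 splits gave as many and the highest other gave 22. For the ATF4 list (9.8e-87) chance is argued against but not excluded. Only the real split (1 of 35) gave so small a camera p for any of the 39 lists (smallest other 1.54e-44, for ribosomal proteins). That is again the smallest share that this design allows, and this test was chosen after its values were seen. On this measure chance stays open for skeletal muscle (3 splits), aminoacyl-tRNA synthetases (11), p53 targets (32), lens (33) and the other lists called. Counted for the same list alone, with no conclusion drawn because the real values were known, the splits with as small a p numbered 1 for ATF4, skeletal muscle, aminoacyl-tRNA synthetases, p53 targets, lens, apoptosis and translation factors, 3 for postmitotic neurons, 5 for inflammation and for neural crest, 7 for ribosome biogenesis, 8 for podocyte, 9 for histone genes, 11 for myeloid cells, 14 for hatching gland and 21 for hox genes.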

How the results depend on the processing

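The fits without wild-type library 4 and mutant library 1 together, the ribosomal protein share as a covariate and the windows of neighbouring genes were chosen only after the data were seen. The count of 7225 changed genes went to 12084 with 1 surrogate variable, 11574 with the ribosomal protein share as a covariate, 11385 with both libraries that stand apart left out (5290 of at least 2-fold, against 3463) and 4119 at an adjusted p under 0.01, where the stricter threshold is the cause; for the others the cause was not tested. Leaving out 1 library at a time gave 5310 to 8602 changed genes, 2938 to 4048 of at least 2-fold, a log2 fold change of osgep from −0.9767 to −0.7331 and 15 to 24 gene lists. The 16 lists fell to 2 with an estimated correlation, a setting that allows for genes moving together. They rose to 21 without a filter, 21 with ranks, 22 with fry and 23 with both libraries that stand apart left out. Lists that passed fry but not camera were interferon response (fry adjusted p = 0.00116), hypoxia (0.00309), retinal (0.00406) and germ line genes (0.0124). Circadian (fry adjusted p = 0.0257), neural progenitor (0.0278) and pronephric tubule genes (0.0359) did so too. The odds ratio of 0.7706 on the osgep chromosome was 0.6916 for the nearest 50 genes on either side (Fisher's exact test p = 0.112), 0.7085 for the nearest 100 (p = 0.0348) and 0.8283 for the nearest 200 (307 genes, as 1 side held fewer than 200, p = 0.144), and the cause was not tested. With a replicate block the values were 7193, 3499, −0.8457 and 17 lists. Deviations of log2 CPM from the genotype mean correlated at 0.651, 0.169, −0.266 and 0.0895 between same-numbered libraries, so the numbers were not used as pairs. Of 163 named genes, 152 stayed on their side of the threshold in all alternatives, 11 lost the call in some and 0 reversed. Translation factors lost the call with ranks (adjusted p = 0.147). Windows in base pairs and the ANN codon comparison were not run. In the simulated data most changes of 1.5-fold were not called, but far fewer genes changed there than were called here. The share of changes under 2-fold that was missed in these data is therefore not known.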

Other observations

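The lists described here were chosen only after the data were seen. Genes of somite segmentation and the tailbud moved in both directions: of 19 tested, 4 rose and 2 fell, in both adjustments. As a list they did not pass (camera p = 0.319, and p = 0.736 with an estimated correlation). The retinoic acid degrading enzyme gene cyp26a1 rose from 11.4 ± 2.71 to 49.1 ± 5.05 CPM and the clock gene her11 from 2.13 ± 0.398 to 5.25 ± 0.812 CPM, while the Delta ligand gene dlb fell from 213 ± 33.4 to 113 ± 14.2 CPM. Among 13 early myogenic regulators 2 fell and none rose in both adjustments: pax7b went from 47.6 ± 3.77 to 25.5 ± 3.59 CPM and mef2ca from 196 ± 19.3 to 130.1 ± 15.9 CPM. All genes in this paragraph are named after their values were seen.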
